A study of Brassica napus with 6 samples.

How the data were processed

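The series measured messenger RNA by sequencing in 6 libraries of Brassica napus (oilseed rape), genotype DH12075, with 3 biological replicates in each of 2 groups. Late unicellular microspores, the haploid cells that become pollen, were isolated and cultured. In the treated group, heat stress at 33 °C was combined with trichostatin A (TSA), an inhibitor of histone deacetylases, at 0.05 µM for 24 h. The control cultures were kept at 25 °C to let pollen develop. The labels' treatment protocol gives them the solvent DMSO, while their treatment label calls them untreated. All cultures were washed, returned to 25 °C and collected on day 2. The labels name microspores and pollen in the control group and add embryogenic cells to these in the treated group. RNA was extracted after bead disruption and libraries were made with a TruSeq RNA kit, per the labels' protocols. Samples were grouped by their titles, and each column of the table was assigned to the sample whose description it repeats.

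The deposited values are whole-number read counts per gene model, 1 column per library, with no normalization. TopHat2, a spliced read aligner, and HTSeq, a read counter, are named in the submitters' processing notes, without versions. The genome build, the annotation release, the strand setting and the treatment of reads that map to more than 1 place are not given in the sources used here. Brassica napus is an allotetraploid with closely related A and C subgenomes, so the treatment of such reads can move counts between near-identical copies, and the value of any single identifier carries that uncertainty. The table lists 101040 identifiers, none of which is a summary line or a column of another sample. Identifiers are given without gene names. None of them (0 of 101040) matched an entry of the available RefSeq gene table for the Da-Ae assembly, which holds 123214 genes. The 16 gene lists fixed before the data were examined, which covered heat shock, embryo, pollen, cell division and chromatin genes among others, therefore could not be matched to any identifier (0 of 16), and no list or set test was run. Positions and functions of the identifiers are not reported for the same reason.

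Library totals ranged from 11758677 to 24773444 counts. The counts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on a model with group alone, after trimmed-mean (TMM) scaling and edgeR's filterByExpr with its minimum count of 10. This left 49871 identifiers. P-values were adjusted by the Benjamini-Hochberg method over these, with a threshold of 0.05, and an identifier past it is called higher or lower. Fold changes are on the log2 scale, heat stress plus TSA relative to pollen culture. CPM values (counts scaled by library size) were computed from the deposited counts with TMM-scaled totals. An identifier was described as near-silent in a group when its reads summed to at most 3 over the 3 libraries, and folds against a group without any read were computed as lower bounds, the mean CPM of the other group over the CPM that 3 counts over the silent group give. Ratios against 1 to 3 counts were taken from the reads summed per group, scaled by library size, and carry 95% exact (Clopper-Pearson) intervals. These intervals and bounds cover counting error only, since the reads carry no molecular identifiers. To compare the number of identifiers detected at equal library totals, each library was thinned at random to 11758677 counts. Single values per library were compared between groups with a two-sided exact permutation test, which cannot give a p below 0.1 with 3 libraries against 3. The pairwise chi-square statistic per degree of freedom of the counts was at least 10.2 in every pair of libraries, over identifiers with 20 or more reads, so no pair was a repeat of 1 library within sampling noise.

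By a rule fixed before the data were examined, where identifiers cannot be paired with names the text names the 2 with the largest fitted rise and the 2 with the largest fitted fall among those past the threshold, with an average log2 CPM of at least 3 and no overlap between the groups' libraries. The main fit was tested on simulated data: negative binomial counts for the 49871 identifiers with the means, dispersions and library sizes of these libraries, and 200 identifiers changed by known folds. At an adjusted p of 0.05, edgeR recovered 0 of 50 identifiers changed 2-fold, 11 of 50 changed 4-fold, 35 of 50 changed 8-fold and 44 of 50 changed 16-fold, with 9 false calls among 99. Changes of 2-fold were thus missed in the simulation, although 29 of the calls made on the real data were under 2-fold. The simulation changed 200 identifiers, all averaging at least 1 CPM, while 4529 were called in the data. Fewer true changes make the Benjamini-Hochberg cut stricter, so these recovery rates cannot be carried over to the data. The 9 false calls are a larger share of the 99 than the 0.05 aimed at, in 1 simulated data set. Its libraries were drawn independently, without the shift shared by the replicate 1 libraries of the data, so that share cannot be carried over either.

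Alternatives fixed beforehand were median-of-ratios and upper-quartile factors, library size alone, DESeq2 1.42.0, limma-voom (limma 3.58.1), no filter beyond 1 read, a filter of 1 CPM in 3 libraries, the replicate number as a block, removal of the 50 most abundant identifiers, thinning, and leaving out each library in turn. A term for replicate 1 of both groups, and a fit to replicates 2 and 3 alone, were added after the data had been seen, because the replicate 1 libraries stood apart. TMM-scaled CPM for the number of identifiers detected was also added then.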

Results

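Transcript levels were measured in microspore cultures of Brassica napus on day 2, to compare cultures led toward haploid embryogenesis by heat stress plus the histone deacetylase inhibitor TSA with cultures left to develop into pollen. Each group held 3 libraries. The pollen-culture libraries held 14714537, 24527873 and 19841078 counts for replicates 1 to 3, and the heat stress plus TSA libraries held 11758677, 24773444 and 22920440. Of the 101040 gene identifiers, 21526 (21.3%) had no read in any library and 49871 had enough reads to be tested. Temperature and TSA changed together between the groups, so each difference below is that of the combined treatment and cannot be assigned to either part. All libraries were collected on day 2, and the starting microspores were not among them. A rise or fall below is thus a difference between the groups, and which group moved is not known.

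The transcriptomes of the 2 groups were distinct, and the libraries were also divided by replicate number. The first principal component of log2 CPM took 58.5% of the variance and placed the 3 heat stress plus TSA libraries opposite the 3 pollen-culture libraries. The second took 26.2% and placed replicate 1 of both groups apart from replicates 2 and 3. Pearson's r of log2 CPM, across identifiers, was 0.980 between pollen-culture replicates 2 and 3 and 0.955 between heat stress plus TSA replicates 2 and 3. It was 0.915 and 0.896 between pollen-culture replicate 1 and its partners, and 0.865 and 0.857 for heat stress plus TSA replicate 1. Between groups it ran from 0.715 to 0.831. Identifiers are not independent replicates, so these values describe the libraries. The labels give no batch, so replicate 1 of both groups was treated as a possible batch and the main comparison was repeated with and without it.

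**Figure D1:**
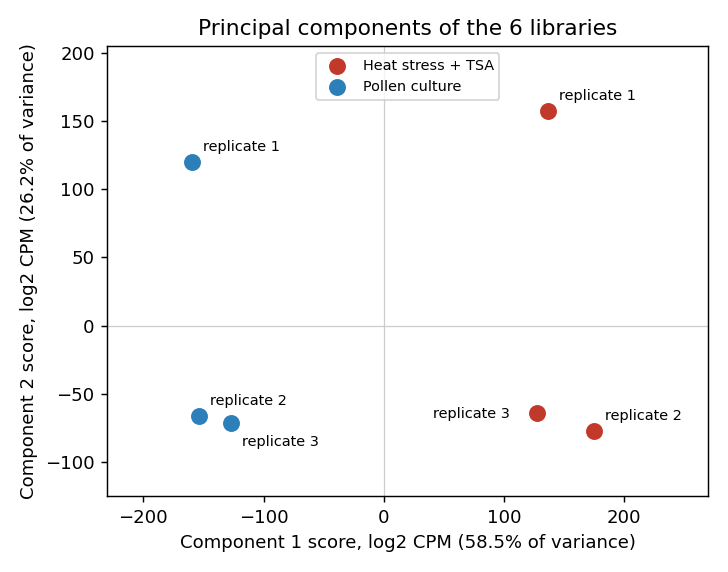
Scores of the 6 libraries on the first (58.5% of variance) and second (26.2%) principal components of log2 CPM; each point is 1 library, coloured by group and labelled by replicate. The groups separate along the horizontal axis, and replicate 1 of both groups lies above replicates 2 and 3 along the vertical axis.

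More genes rose than fell with heat stress plus TSA. At an adjusted p of 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), 3320 identifiers (6.66% of those tested) were higher and 1209 (2.42%) were lower after heat stress plus TSA than in pollen culture. The higher set rose by a median of 11.2-fold (log2 3.48, quartiles 2.29 and 5.32) and the lower set had a median log2 fold change of -3.98 (quartiles -5.56 and -2.56). With identifiers that had no read in one group set at their lower bound, the medians were 3.47 and -3.96. Of the 4529 calls, 4500 were at least 2-fold, 1380 were fitted at least 16-fold higher and 600 at least 16-fold lower, or 1351 and 594 at their bounds. In each of the 4529 called identifiers the libraries of the groups did not overlap. Such separation was seen in 27.7% of all tested identifiers (8251 higher and 5554 lower), against 10% by chance for 3 libraries against 3. With replicates 2 and 3 of each group alone, edgeR called 6520 higher and 2303 lower, and with a term for replicate 1 it called 5526 higher and 2382 lower. DESeq2 on all 6 libraries called 5222 higher and 2059 lower, with 7123 at least 2-fold. It was run without the filterByExpr step, on 79514 identifiers, so method and filter changed together. The edgeR counts fell by over 1.5 times when single libraries were left out, to 781 higher and 450 lower without pollen-culture replicate 2, 1283 and 628 without pollen-culture replicate 3, and 1251 and 612 without heat stress plus TSA replicate 2, while without heat stress plus TSA replicate 3 the higher set fell to 1829. The calls of at least 2-fold fell to 1231, 1911 and 1863 in the first 3 of these, and the median log2 fold change over all 6 such fits ran from 3.92 to 5.87 for higher and from -5.66 to -3.69 for lower calls. That median was 2.35 and -2.13 with the term for replicate 1, 3.003 and -2.41 with replicates 2 and 3 alone, and 3.26 and -3.001 by DESeq2, each over its own calls. Passing the test favours large changes, so these medians describe the called identifiers and not the typical response.

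**Figure D2:**
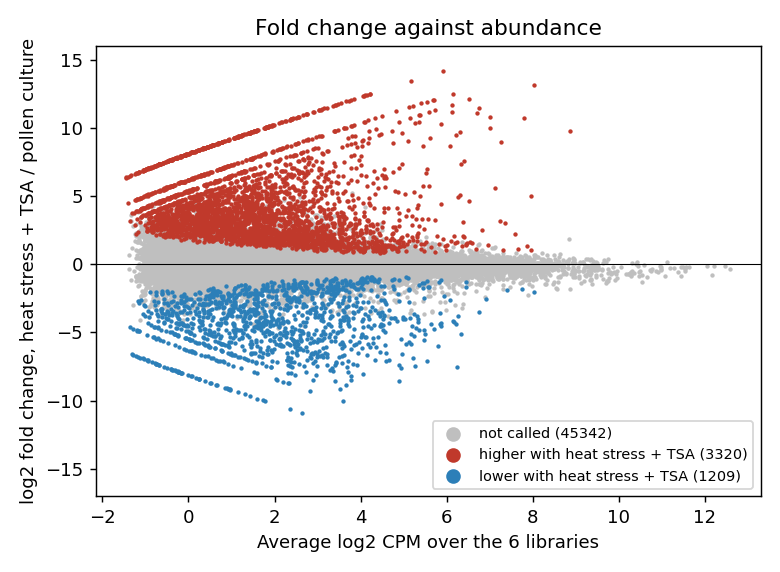
Log2 fold change (heat stress plus TSA over pollen culture) against average log2 CPM for the 49871 tested identifiers; red points are the 3320 called higher, blue points the 1209 called lower and grey points those not called. The slanting lines at the edges are identifiers with no read or few reads in one group, whose fitted fold change depends on the prior count.

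Most genes called in replicates 2 and 3 moved in that direction in the replicate 1 pair too, whose 2 libraries took no part in those calls. The log2 ratio in that pair is heat stress plus TSA replicate 1 over pollen-culture replicate 1. Of the 6520 identifiers called higher in replicates 2 and 3, 6041 (92.7%) had a ratio above 0 in the replicate 1 pair. The share over all identifiers tested was 52.2%. Any ratio above 0 was counted, including some of 0.001 to 0.003 where the 2 libraries were nearly equal. Of the 2303 called lower, 2010 (87.3%) had a ratio below 0, for which no share over all identifiers was computed. On a log2 scale with a prior count of 2, the median ratio of the higher set was 2.58 in replicates 2 and 3 and 1.49 in the replicate 1 pair. The median of the lower set was -2.19 in replicates 2 and 3, and that of the replicate 1 pair was 0.19 nearer to 0. The replicate 1 pair has 1 library per group, so no test was made within it. Identifiers picked for their change in replicates 2 and 3 have that change overstated there. The values that follow are for the sets called from all 6 libraries, so likeness among the treated libraries is partly built in. They use a prior count smaller than 2 and are not comparable with the medians above. The median log2 difference of a library from the pollen-culture mean was 3.14, 3.97 and 3.78 for the higher set in heat stress plus TSA replicates 1, 2 and 3 (mean 3.63 ± 0.44, SD, n = 3). For the lower set it was -4.79, -4.54 and -3.27 (mean -4.20 ± 0.82, SD, n = 3).

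A group of genes was near-silent in pollen culture and expressed, mostly under 10 CPM, after heat stress plus TSA. A smaller group showed the reverse. Of the 3320 higher identifiers, 803 had at most 3 reads over the 3 pollen-culture libraries together, and 276 of these had none. Their median level after heat stress plus TSA was 2.34 CPM (quartiles 1.25 and 5.41), and 126 averaged at least 10 CPM. Of the 1209 lower identifiers, 213 had at most 3 reads over the 3 heat stress plus TSA libraries, and 59 of these had none. Their median level in pollen culture was 2.21 CPM (quartiles 1.36 and 3.97), with 14 at 10 CPM or more. In fits with fewer libraries the limit of 3 reads was kept, so it is easier to meet where the silent group has 2 libraries. Counted this way, the number of near-silent genes that rose was 1864 with replicates 2 and 3 alone. It was 1403 without heat stress plus TSA replicate 1, 467 without heat stress plus TSA replicate 2 and 389 without pollen-culture replicate 2. It was 1444 by DESeq2, which was also run without the filterByExpr step. By edgeR it was 1273 with no filter on low counts and 452 with a filter of 1 CPM in 3 libraries. The number that fell was 324 with replicates 2 and 3 alone, 445 without heat stress plus TSA replicate 3 and 121 without pollen-culture replicate 2.

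Among identifiers with an average log2 CPM of at least 3, the 2 largest fitted rises over all 6 libraries were in identifiers without any read in the 3 pollen-culture libraries. GSBRNA2T00093535001 reached 63.5, 129 and 168 CPM in heat stress plus TSA replicates 1 to 3 (mean 120 ± 52.8, SD, n = 3), at least 2259.9-fold higher than 3 counts over the pollen-culture group would give (edgeR adjusted p = 0.00198). GSBRNA2T00045280001 reached 7.41, 56.0 and 154 CPM (mean 72.3 ± 74.4, SD, n = 3), at least 1359-fold higher (edgeR adjusted p = 0.0166). Fitted folds against 0 reads depend on the prior count, so the order of such identifiers is that of this fit only. The level of GSBRNA2T00045280001 varied widely between the treated libraries, and its adjusted p rose to 0.0585 without pollen-culture replicate 2. Its fitted log2 fold change of 13.46 was 12.25 without heat stress plus TSA replicate 3. The 2 largest fitted falls under the same limits were in identifiers with almost no reads after treatment. GSBRNA2T00011949001 stood at 24.0 ± 5.51 CPM (SD, n = 3) in pollen culture, from 1309 reads, and had 1 read in the heat stress plus TSA libraries, a ratio of scaled reads of 1403 with a 95% counting interval of 251 to 55476 (log2 fold change -10.03, SE 0.62, edgeR adjusted p = 0.00102). GSBRNA2T00120125001 stood at 22.7 ± 8.04 CPM (SD, n = 3), from 1221 reads, and had 2 reads after treatment, a ratio of scaled reads of 655 with an interval of 181 to 5411 (log2 fold change -9.12, SE 0.82, edgeR adjusted p = 0.00189). Each SE is the fitted log2 fold change divided by the square root of its F statistic. It is far narrower than the counting interval and does not give the precision of the fold. The few reads after treatment set these folds. The log2 fold change of GSBRNA2T00011949001 was -11.84 without heat stress plus TSA replicate 3, which held its 1 read, and -9.44 without heat stress plus TSA replicate 2. That of GSBRNA2T00120125001 was -11.90 without heat stress plus TSA replicate 1, which held its 2 reads, and -8.44 without heat stress plus TSA replicate 2.

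**Figure D3:**
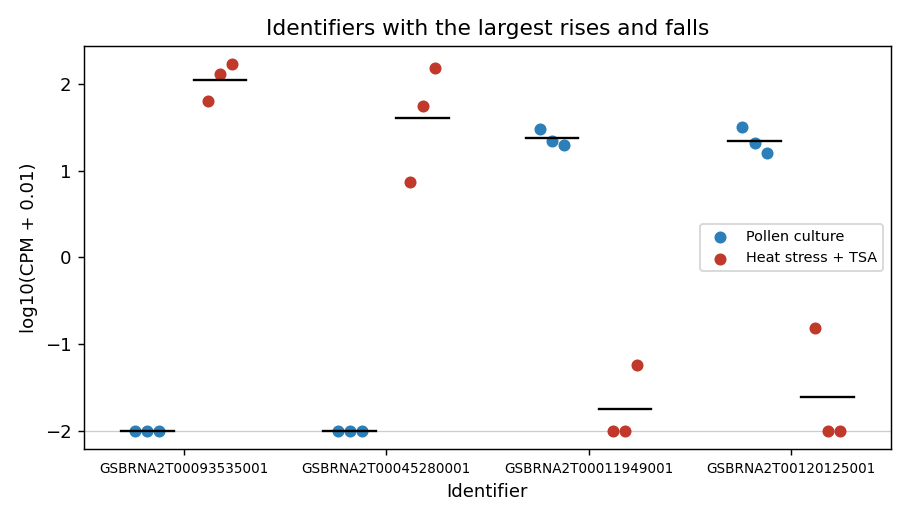
Level of the 4 named identifiers in each library as log10(CPM + 0.01); points are libraries in the order of replicates 1 to 3 within each group, bars are group means on that scale, and -2 marks 0 reads. The 2 identifiers on the left have no read in pollen culture and the 2 on the right have at most 2 reads in the treated group.

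A larger share of genes was called at low than at high average abundance, and 76 of the 100 most abundant identifiers of each group were in common. The average is taken over both groups, so a gene silent in one group is placed lower by its own change, and part of this trend is built in. Below an average log2 CPM of 0, 595 of 4942 identifiers were called higher and 171 lower. Between 4 and 6, 2.21% were called higher and 1.31% lower. At 8 and above, 2 of 304 identifiers were higher and 1 was lower. None of the 100 most abundant identifiers was called by edgeR, although 3 had an unadjusted p under 0.05. DESeq2 called 3 of them, all lower, and limma-voom called 0. Their median absolute log2 fold change was 0.45 and the largest was 1.42. The lack of edgeR calls does not show that these identifiers were unchanged, since the same fit missed 2-fold changes in the simulation. The 3320 higher identifiers took 4.02% ± 0.78 (SD, n = 3) of the counts after heat stress plus TSA and 0.563% ± 0.068 in pollen culture. The 1209 lower identifiers took 0.237% ± 0.038 and 1.69% ± 0.16. These sets were chosen on the same libraries, so the shares describe them and do not test them.

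**Figure D4:**
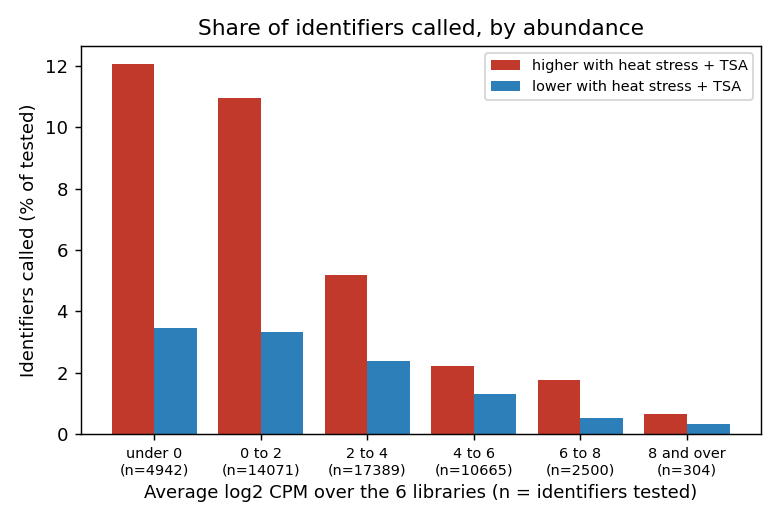
Percentage of tested identifiers called higher (red) or lower (blue) after heat stress plus TSA, by average log2 CPM over the 6 libraries; n under each pair of bars is the number tested. The share called higher falls from 10.9% between 0 and 2 to 0.658% in the highest class.

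More genes were above 1 CPM in the treated cultures when library totals were made equal. With every library thinned to 11758677 counts, 43874 ± 617 identifiers (SD, n = 3) reached 1 CPM, or 12 reads, after heat stress plus TSA and 41004 ± 1116 in pollen culture. Every treated library was above every control library, with an exact two-sided permutation p of 0.1, the smallest that 3 libraries against 3 can give. The difference held within the possible batches, with 43920 against 40711 in the replicate 1 pair and means of 43852 against 41151 in replicates 2 and 3. Equal totals do not make the reads left for the less abundant genes equal. With TMM-scaled CPM in the thinned libraries, an alternative added after seeing the data, the numbers were 43470 ± 719 and 41231 ± 872 (SD, n = 3), again with every treated library above every control library (exact permutation p = 0.1). The number of identifiers with any read at that total was 64005 ± 803 against 61382 ± 1630, with overlapping groups (exact permutation p = 0.2). The share of counts taken by the 100 most abundant identifiers of each library, 13.1% ± 4.3 after treatment and 16.1% ± 1.4 in pollen culture (SD, n = 3), differed by less than the spread between treated libraries (exact permutation p = 0.3).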

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

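The term for replicate 1, the fit to replicates 2 and 3 alone and the TMM-scaled CPM of the thinned libraries were chosen after seeing the data; the other settings were fixed before the data were examined. No called identifier of the main comparison changed sign under any of the 18 alternatives that tested it. The groups' libraries did not overlap in any of these identifiers, so a change of sign was unlikely from the start. The kept signs therefore lend little support. The number of identifiers at 1 CPM was higher after treatment by 2870 with CPM by library total and by 2239 with TMM-scaled CPM. Counts of higher and lower calls stayed within 1.5 times of 3320 and 1209 under the 3 other scalings, limma-voom, both filters, thinning, removal of the 50 most abundant identifiers and the block. Leaving out a library gave 781 to 4307 higher and 450 to 1362 lower calls, 1231 to 5628 at least 2-fold calls, 389 to 1403 near-silent identifiers that rose and 121 to 445 that fell. In each of these ranges but the last the highest value came without heat stress plus TSA replicate 1, and all the lowest came without pollen-culture replicate 2, which leaves the outlying pollen-culture replicate 1 with 1 partner. DESeq2, run on 79514 identifiers without the filterByExpr step, called 5222 higher, 2059 lower, 7123 at least 2-fold and 1444 near-silent that rose. Its method and filter thus changed together. The term for replicate 1 called 5526 higher, 2382 lower and 6974 at least 2-fold. Replicates 2 and 3 alone gave 6520 higher, 2303 lower, 8009 at least 2-fold, 1864 near-silent that rose and 324 that fell; they shared 3252 higher and 1167 lower calls with the fit to all libraries. The limit of 3 reads was kept where the silent group had 2 libraries, which widens that class by construction. Near-silent identifiers that rose numbered 1273 with no filter and 452 with at least 1 CPM in 3 libraries, which removes low identifiers by construction. Library size alone moved the median log2 fold change of all tested identifiers from -0.01 to 0.12; for the other differences the cause was not tested. Of the 4 named identifiers, 3 stayed past the threshold under every alternative (highest adjusted p 0.0112 to 0.0148), and GSBRNA2T00045280001 missed it in 1, at 0.0585.

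The replicate numbers did not pair the libraries by the rule set for this: same-numbered deviations from the group means correlated at 0.50, 0.42 and 0.02 for replicates 1, 2 and 3, and 3 of the 6 libraries correlated best with their own number. The fit with the replicate number as a block called 3785 higher and 1544 lower. The set tests and list counts planned for the 16 gene lists were not run because no identifier could be matched to a list. Depth limits the near-silent sets, since 3 reads over a group correspond to about 0.053 CPM in pollen culture and 0.050 CPM after treatment.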

Other observations

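Of the tests below, those of the term for replicate 1 against the treatment difference, and of the scalings, were chosen only after the result was seen. No identifier has a known function here, so these observations concern groups of identifiers.

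Replicate 1 of both groups differed from replicates 2 and 3 in 8900 identifiers, 4208 higher and 4692 lower, in a model with group and a term for replicate 1 (edgeR, adjusted p of 0.05), with a median absolute log2 fold change of 1.29. In that same model the treatment called 7908, 5526 higher and 2382 lower, and the overlaps that follow are with these. Identifiers higher in replicate 1 and raised by the treatment numbered 213, where independent lists would share 466. Identifiers lower in replicate 1 and raised by the treatment numbered 675 against 520. Among the 2382 lowered by the treatment, 170 were higher in replicate 1 against 201 for independent lists, and 136 were lower against 224. The 6 libraries serve both comparisons, so these overlaps describe the data and were not tested.

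Replicate 1 of both groups stands apart although the labels name no batch. Its libraries are the shallowest, but thinning all libraries to the smallest total left 8228 calls of the term, so depth alone does not account for it. Leaving out the 50 most abundant identifiers left 8809. TMM scaling already trims extreme identifiers, so that removal says little on whether a few abundant genes set the scale. Across identifiers the fold changes of the term and of the treatment correlated weakly (Pearson's r = -0.14, Spearman's rho = -0.03), which neither excludes nor shows that replicate 1 lies elsewhere along the treatment axis. A batch of preparation or sequencing, and a different stage of the isolated microspores, cannot be told apart for the 8900 identifiers, because no label bears on either.

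More identifiers rose than fell, at a ratio of 2.75, which was 1.44 without heat stress plus TSA replicate 3 and 1.74 without pollen-culture replicate 2. The lowest ratio over 4 other scalings was 2.62 and the ratio with equal library totals was 2.48. More identifiers thus rose than fell under each of these scalings. All of them rest on relative abundance, so a shift that all of them miss could still be the source. The mean library totals of the groups hardly differed (exact permutation p = 0.9). Thinning therefore had almost no depth difference between the groups to remove, and it cannot decide whether depth is the source. Among identifiers with an average log2 CPM of at least 3 the ratio was 1.85 (623 higher, 337 lower), so part of the excess may come from low counts passing the test more easily in 1 direction. By class of abundance the ratio was 3.48 below 0, 1.69 from 4 to 6 and 3.38 from 6 to 8 (44 higher, 13 lower), and the last, on few calls, goes against low counts as the whole source without settling it. The labels list embryogenic cells besides microspores and pollen in the treated cultures. A broader set of expressed genes there is a possible biological alternative, which the labels do not state. It was not tested beyond the counts with equal library totals.

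Calls in 1 direction sat next to each other in the order of the identifier numbers more often than chance. There were 233 next-in-line pairs called in the same direction, against 141 ± 11.9 (mean ± SD) in 1000 permutations of the calls within 20 classes of expression, none of which exceeded 177 (p = 0.001, the smallest they can give). At 2 places apart there were 147 pairs against 131 (permutation p = 0.068), at 3 to 10 places 1059 against 1011 (permutation p = 0.067), and at 11 to 20 places 1250 against 1250. An excess past all permutations at direct neighbours alone, among these distances, is consistent with gene models split in the annotation or adjacent duplicate copies that share reads, if the numbers follow the genome, which no source used here states. Adjacent genes that are truly regulated together would give the same picture and remain open.

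The 6 libraries can be split into 3 and 3 in 10 ways. The real split gave 3320 higher, 1209 lower and 4500 at least 2-fold calls, and 1 of the 10 splits, the real one, reached each of these values. The highest of the other splits was 0 for each (edgeR), with 72 to 3526 identifiers at an unadjusted p under 0.05 in those splits against 10220 in the real one. With 10 splits the share cannot fall under 0.05. Each of the other splits mixes treated and control libraries on both sides. The difference between the groups then adds to the spread within each side and lowers the calls. The 0 calls there therefore give no support to the real split.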
